A study of Mus musculus with 6 samples.

How the data were processed

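Ventricles of 6 male C57BL/6 mice were frozen, total RNA was extracted, and stranded polyA libraries were sequenced as paired ends of 151 bases, per the labels' protocols. The labels put 3 mice in the sham group and 3 in the pacing group, and the series design describes separate animals, so that the gene p-values measure the spread between mice. The list p-values at a preset correlation compare a list's genes with the other genes. They do not measure how the level of a list varies between mice. The submitters' processing notes name FastQC 1.0.0, TopHat2 2.1.0, Bowtie2 2.2.6, Cufflinks, Cuffdiff and the mm10 build, and the gene annotation, filters and settings are not given in the sources used here.

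The authors deposited an FPKM value for each gene and mouse (24239 rows), that is fragments per kilobase scaled to the size of the library, with 0.01 written where no fragment is reported. The authors' deposited comparison table (24341 rows) holds an FPKM value per group, a log2 fold change of pacing over sham, a q-value and a call, per the file headers, with the call at a q under 0.05. The median ratio of the mean over mice to the group FPKM was 1.01 in both groups. In the fold column 405 cells hold a spreadsheet error in place of a negative infinite fold, 27 gene names had been turned into dates, and 102 rows, most of which merge several genes, are in the comparison table alone. The value of Cacna2d1 in sham 2 is a failed estimate, so this gene was left out. Symbols and coordinates are those of the deposited tables, with starts counted from 1. Stranded libraries were used, but the strand setting of the counting is not given, so antisense overlaps were not separated here.

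FPKM is not a count, so no count model was fitted. The lowest values of 644 genes with 1 exon and 1 transcript, between 800 and 3000 bases long, were whole multiples of the value of 1 fragment in 100% of values under 10 fragments, within 0.05 of a fragment and with the length shortened by 166 bases, which gave the effective depth of each library, from 6276000 to 8907000 fragments. Sums of FPKM ranged from 658699.9 to 756535.1. Counting error alone gives a coefficient of variation of 31.6% at 10 fragments. No library shared more than 0.014% of its values above the floor with another, so none is a copy of another. Each was kept as a separate mouse on the word of the series design, which this check cannot test.

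Genes with a mean FPKM of at least 1 were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, group as the only term), two-sided, with Benjamini-Hochberg adjustment over 11994 genes. The 45 gene lists, with 1211 distinct genes of which 1037 were tested, were fixed before the data were examined, as were the gene and list tests, the rule for named genes and the alternatives other than those named below as added. The tests of atrial, lung and fat markers were chosen after the results were seen. Lists with at least 5 genes were tested with camera at a preset correlation of 0.01 and adjusted over 42 lists, and again with an estimated correlation and with fry. Not tested were the mitochondrially encoded genes, of which 0 of 13 are in the table, the neutrophil markers, with 2 genes left, and the T and B lymphocyte markers, with 3. Members were also adjusted over the list alone.

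The rule for named genes took, as none passed, the 10 genes with the smallest p in each direction, up to 4 members of each passing list and 2 of each other list, all 24 panel genes, and the 5 largest called changes in each direction of the authors' deposited table with a mean FPKM of at least 1. Genes outside this rule that the text names were chosen after their values were seen, as Cfd, Cyp2e1, Rbp4, Myl7, Sln, Bmp10, Hba-a2, Ppbp, Pf4, S100a9 and Ucp1 were. Some of the genes that this rule took are not reported here. For Gdf15, below the filter, an exact permutation test was used.

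The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5, rescaling to the same sum, centring on medians, quantile normalization, eBayes without a trend or robust, array weights, a block by replicate number, an adjusted p under 0.1, repeated names left out, each mouse left out in turn and, for the authors' table, stricter thresholds. Added after seeing the data were a covariate for the level of atrial genes (Myl7, Myl4 and Sln), a covariate for adipocyte genes (Adipoq, Plin1 and Cidec), and a fit without pacing 2 and pacing 3. Simulated data had the real means, 11994 genes and 3 libraries per group. In each of 20 simulations 200 genes were changed, 100 by 1 and 100 by 2 on the log2 scale. The gene test recovered 85.4% of changes of 1 and 97.4% of changes of 2, with 8.6 false calls per simulation. Many changed genes make the adjusted threshold easier to reach, so this recovery need not hold where few genes change. Each of 20 lists shifted by 0.5 was called, with 0.1 lists called per simulation where nothing had changed. The simulated genes varied independently, which real genes do not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.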

Results

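Ventricular RNA from 6 male C57BL/6 mice aged 8 to 10 weeks was measured by stranded polyA RNA sequencing, with 3 sham mice and 3 mice after 8 days of atrial pacing. Pacing was delivered through a bipolar catheter in the esophagus, which lies next to the atria, and drove the heart at a cycle length of 80 ms for 45 min a day between 3 min periods at 120 ms. It was given on 5 days and, after 2 days of rest, on 3 more days. The comparison asks which ventricular transcripts differ after repeated fast pacing from the atrium. Each mouse has 1 FPKM value per gene. The steps of the lowest values put the effective depth at 7808000, 7888000 and 6276000 fragments in sham 1, 2 and 3. In pacing 1, 2 and 3 it was 8078000, 7746000 and 8907000 fragments. An FPKM of 1 on an effective length of 2 kb, that is after the shortening, stands for 12.55 to 17.81 fragments. Values are mean FPKM ± SD over 3 mice per group unless stated, and fold changes are pacing minus sham on the log2(FPKM + 1) scale, which understates the change of low genes.

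In the ventricles of paced mice, transcripts of inflammatory mediators, of connective tissue and of 1 list of red cell and platelet markers lay higher than in sham mice. In that list the platelet gene Ppbp was higher, while the platelet gene Pf4 had a similar mean in both groups. Transcripts of the respiratory chain and of blood vessel growth lay lower, each as a group. The mean respiratory chain level of sham 1 nevertheless lay within the range of the paced mice. All of these list calls rest on a preset correlation between genes, and with an estimated correlation no list passed (lowest adjusted p = 0.281). Markers of fat, atrial muscle and lung were higher in the paced group too (median log2 fold change 1.75, 1.27 and 2.47). With the adipocyte level as a covariate the fibroblast and respiratory chain calls ended (camera adjusted p = 0.277 and 0.305) and collagen genes turned lower (0.0218). Of this covariate's genes, Adipoq and Cidec were higher in each paced mouse than in each sham mouse, and Plin1 overlapped. The covariate is thus tied to the group, and such a fit cannot separate fat content from an effect of pacing. No gene passed the adjusted threshold alone. Among the genes with the smallest p, Ccl8, a chemokine that attracts monocytes, stood at 0.80 ± 0.386 in sham and 9.44 ± 3.81 in paced ventricles (log2 fold change 2.48, SE 0.29, limma adjusted p = 0.107). Serpina3n, an acute phase protease inhibitor, stood at 4.52 ± 0.937 and 13.6 ± 3.66 (log2 fold change 1.39, SE 0.19, limma adjusted p = 0.20). Further genes in this direction were Nbl1, an antagonist of bone morphogenetic proteins, at 9.94 ± 0.665 and 20.4 ± 3.65, and Htra4 at 1.75 ± 0.211 and 4.09 ± 0.572. Tmem100 stood at 12.0 ± 1.31 and 19.1 ± 0.684, and Figf, the lymphatic growth factor VEGF-D, at 1.66 ± 0.313 and 3.93 ± 0.515. Retnla stood at 15.5 ± 3.81 and 40.2 ± 10.4, Fmo2 at 24.7 ± 1.15 and 40.2 ± 6.37, and the glutathione transferase Gsta3 at 10.0 ± 1.63 and 16.7 ± 1.15.

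On the lower side, Aplnr, the apelin receptor of endothelial cells, stood at 24.1 ± 1.06 in sham and 15.5 ± 2.34 in paced ventricles (log2 fold change -0.61, SE 0.11, limma adjusted p = 0.287). Klhdc8a stood at 6.80 ± 0.590 and 3.74 ± 0.854 (log2 fold change -0.73, SE 0.14) and Cd93, an endothelial adhesion receptor, at 18.4 ± 0.918 and 13.2 ± 0.988 (log2 fold change -0.45, SE 0.09). Klhl30, Sh3bgr, the endothelial protocadherin Pcdh12, Gbp9, the interferon-induced chemokine Cxcl9, the membrane repair gene Dysf and the nucleoside transporter Slc28a2 followed, with log2 fold changes of -0.43, -0.38, -0.54, -0.38, -0.61, -0.36 and -0.45. Ccl8 passed with a replicate block (limma adjusted p = 0.0486), without sham 1 (0.0145) and without pacing 3 (0.0144), over a range of 0.0144 to 1.0 across alternatives. The 3 paced values of each of these genes lay on the same side of the 3 sham values. In mm10 coordinates Ccl8 lies on chromosome 11 from 82115185 to 82116799. Serpina3n lies on chromosome 12 from 104406708 to 104414329 and Aplnr on chromosome 2 from 85136360 to 85139923.

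**Figure D1:**
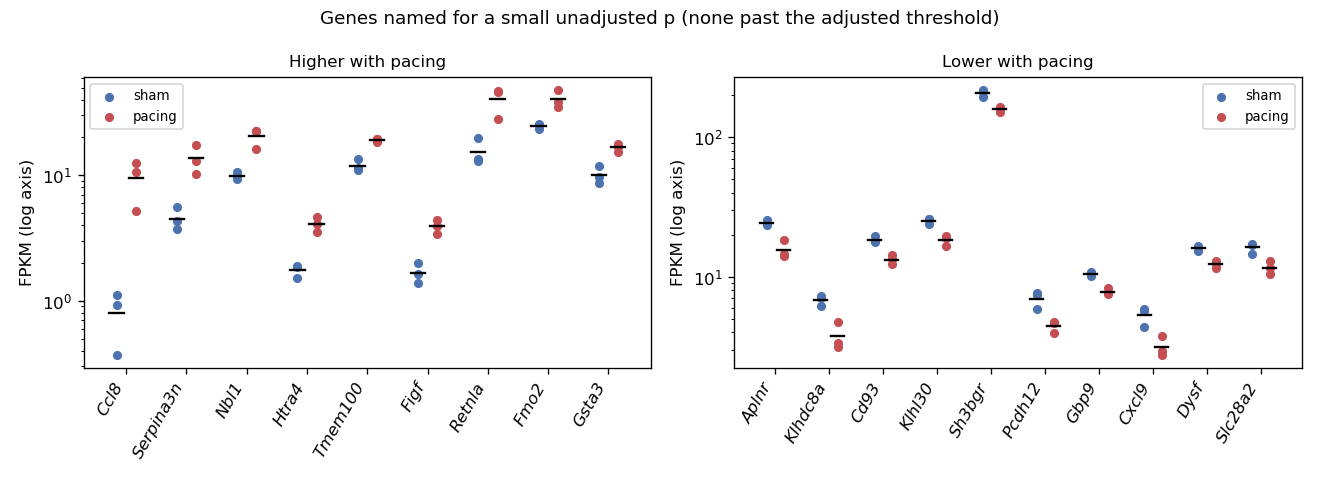
FPKM in each mouse, on a log axis, of genes named for their small unadjusted p in each direction, with sham in blue, pacing in red and the group mean as a black bar. In each gene the 3 paced values lie apart from the 3 sham values, and the adjusted p of each is at least 0.107.

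Of 11994 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.107. At an unadjusted p under 0.05, 620 genes were higher and 442 lower, where about 600 in all would be expected by chance, and 13.2% of genes had no overlap between the groups, where chance gives 10%. The split at an unadjusted p depends on the scaling, with 969 higher and 148 lower after rescaling FPKM to the same sum, 514 and 609 after centring on medians, and 537 and 581 after quantile normalization. Without sham 1, 99 genes were higher and 1 lower at an adjusted p under 0.05, among them Cfd, Cyp2e1, C3 and Rbp4. The fat markers Adipoq, Cidec, Plin1 and Car3 were also among them. Adipoq stood at 27.0 in sham 1 against 2.14 and 1.94 in sham 2 and 3. With the adipocyte level as a covariate, which is tied to the group, the lowest limma adjusted p was 0.748. At an unadjusted p under 0.05, 243 genes were then higher and 165 lower. Without pacing 1, 7 genes were higher and 1 lower, most of them lung genes such as Sftpc and Ager, and without pacing 3 Ccl8 alone was higher. The authors' deposited table, from their own test, called 299 genes higher and 37 lower. Limma gave an unadjusted p under 0.05 for 224 of the 292 of these higher genes it tested and for 37 of the 37 lower ones, and the groups had no overlap in 43.8% of the higher and 73.0% of the lower.

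Among the calls of the authors' deposited table with a mean FPKM of at least 1, the largest increases were in genes of lung epithelium. Scgb3a2, Sftpa1 and Sftpd were listed at 0 in the sham group and at 11.3, 9.56 and 5.66 in the pacing group. Scgb1a1, the club cell secretoglobin, had a log2 fold change of 8.57 and Sftpc, surfactant protein C, of 8.04 in the authors' deposited table. By mouse, Sftpc stood at 1.0, 0.199 and 0.999 in sham 1, 2 and 3, and at 0.195, 153 and 430 in pacing 1, 2 and 3. The largest decreases that the authors' deposited table called were in the transferrin receptor Tfrc (log2 fold change -1.06), the nuclear exporter Xpo4 (-0.99), Klhdc8a (-0.86), Lingo3 (-0.78) and the transporter Slc41a3 (-0.78). Of its 299 higher calls, 60 are in a list of markers of another cell type fixed beforehand.

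Of 45 gene lists fixed before the data were examined, 42 kept at least 5 genes. Of these, 16 rose and 7 fell in paced ventricles at an adjusted p under 0.05 in limma camera with a preset correlation between genes, and 0 did with an estimated correlation, where the lowest adjusted p was 0.281. With fry, which asks whether a list's genes move on balance in 1 direction, 1 list passed, and 2 passed for changes in either direction. No member of any list passed over all genes tested. Covariates for tissue makeup changed the counts, to 10 lists higher and 6 lower with the level of atrial genes and to 10 higher and 5 lower with that of adipocyte genes. With the atrial level the calls ended of cardiac stress (camera adjusted p = 0.104), sarcomere (0.109), collagen (0.155), glycolysis (0.255), citric acid cycle (0.517), fatty acid oxidation (0.509), MHC (0.448), cholesterol synthesis (0.0811), atrial (0.620) and Schwann cell genes (0.0986). With it interferon response (7.71e-07), cell cycle (0.00399) and ribosomal protein genes (0.00189) passed as lower. With the adipocyte level interferon response (2.69e-12), cell cycle (0.00113) and collagen genes (0.0218) passed as lower, and fatty acid oxidation (0.0329) and muscle protein turnover genes (0.0149) as higher. Of the lists that had risen, fibroblast (0.277), macrophage (0.125), MHC (0.0891), cholesterol synthesis (0.878), atrial (0.391), adipocyte (0.152) and Schwann cell lists (0.128) did not pass with it. Without pacing 2 and pacing 3, 11 lists were higher and 4 lower, and the calls ended of cardiac stress (0.395), collagen (0.549), fatty acid oxidation (0.981), glycolysis (0.223), citric acid cycle (0.395), circadian (0.397) and Schwann cell genes (0.749) as well as of mesothelial (0.223) and atrial markers (0.172). Oxidative stress (0.00758) and endoplasmic reticulum stress genes (0.00589) passed without these mice, and lung markers had too few genes left to test.

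Inflammatory cytokine and adhesion genes rose: 26 of 29 tested had a positive fold change, 8 passed when adjusted over the list alone, and the median log2 fold change was 0.36 (camera adjusted p = 2.20e-10, adjusted p = 0.331 with an estimated correlation). Beside Ccl8 and Serpina3n, the siderophore-binding Lcn2 stood at 3.74 ± 1.09 in sham and 8.55 ± 1.89 in paced ventricles, and the alarmin Il33 at 4.95 ± 1.34 and 9.38 ± 2.15. Glucocorticoid response genes rose, with 25 of 29 positive and 6 passing when adjusted over the list alone (camera adjusted p = 1.08e-06, adjusted p = 0.501 with an estimated correlation). Among them the metallothionein Mt2 stood at 36.4 ± 2.77 and 59.4 ± 11.2, Gadd45g at 8.68 ± 0.844 and 11.2 ± 0.209, and Cebpd at 3.98 ± 0.639 and 5.90 ± 0.722. Immediate early genes, which respond to stimuli within minutes, rose with 17 of 19 positive and 0 passing over the list alone (camera adjusted p = 0.000116, adjusted p = 0.331 with an estimated correlation). Klf4 stood at 12.6 ± 0.632 and 16.5 ± 3.46, and Junb at 7.09 ± 0.900 and 8.62 ± 0.235. Macrophage and monocyte markers rose with 22 of 24 positive and 0 passing over the list alone (camera adjusted p = 4.77e-06, adjusted p = 0.535 with an estimated correlation). The lysozyme Lyz1 stood at 1.34 ± 1.07 and 7.13 ± 6.11, and Lyz2 at 203 ± 50.2 and 292 ± 46.8. By mouse, Lyz1 stood at 2.70, 4.58 and 14.1 in pacing 1, 2 and 3, against 2.56 in sham 1. Its rise was thus mainly in pacing 2 and pacing 3, which also held lung transcripts. Lyz2, at 305, 240 and 331 in pacing 1, 2 and 3, did not follow that order. Genes of MHC class I and class II rose with 16 of 16 positive (camera adjusted p = 0.000127, adjusted p = 0.535 with an estimated correlation). H2-T23 stood at 26.4 ± 1.23 and 31.3 ± 3.30. Without sham 2 the MHC call ended (camera adjusted p = 0.146). With the adipocyte level as a covariate the macrophage and MHC lists turned direction and did not pass (camera adjusted p = 0.125 and 0.0891).

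Fibroblast markers rose, with 19 of 20 positive and 7 passing when adjusted over the list alone (camera adjusted p = 8.19e-09, adjusted p = 0.423 with an estimated correlation). The microfibril protein gene Mfap5 stood at 18.9 ± 3.6 in sham and 31.6 ± 3.6 in paced ventricles, Clec3b at 61.2 ± 9.63 and 90.5 ± 13.1, and Fbln1 at 28.3 ± 8.30 and 42.8 ± 3.26. Collagen and matrix genes rose less evenly, with 28 of 40 positive and 0 passing over the list alone (camera adjusted p = 9.12e-05, adjusted p = 0.535 with an estimated correlation). The collagen call ended without sham 3 (camera adjusted p = 0.146), and with the adipocyte level as a covariate the list passed as lower (0.0218), while the fibroblast call ended (0.277). Col14a1 stood at 4.24 ± 1.22 and 7.62 ± 0.617 and the stromelysin Mmp3 at 2.27 ± 1.37 and 4.88 ± 0.357. Mesothelial and epicardial markers rose with 12 of 12 positive and 1 passing over the list alone (camera adjusted p = 7.10e-08, adjusted p = 0.501 with an estimated correlation). They did not pass without pacing 2 and pacing 3 (camera adjusted p = 0.223). Complement C3, in this list, stood at 54.2 ± 23.9 and 137 ± 14.9, and mesothelin, Msln, at 9.54 ± 4.09 and 18.5 ± 6.04. Fat markers were also higher in the paced mice and in sham 1: Adipoq, which encodes adiponectin, stood at 27.0, 2.14 and 1.94 in sham 1, 2 and 3 and at 72.8, 36.2 and 28.6 in pacing 1, 2 and 3.

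Adipocyte markers rose with 13 of 13 positive, 7 passing over the list alone and a median log2 fold change of 1.75 (camera adjusted p = 5.71e-07, adjusted p = 0.501 with an estimated correlation). The lipid droplet gene Cidec stood at 5.23 ± 7.11 and 27.1 ± 13.7 and Car3 at 31.8 ± 42.5 and 171 ± 87.0, so that the SD of the sham mice was larger than their mean. Cholesterol and lipid synthesis genes rose, with 20 of 29 positive and 0 passing over the list alone (camera adjusted p = 0.0115, adjusted p = 0.501 with an estimated correlation). Without sham 3 they did not pass (camera adjusted p = 0.0501). The members that moved most make fatty acids, namely Scd1 at 25.9 ± 28.3 and 102 ± 24.6 and Fasn at 8.58 ± 8.22 and 25.9 ± 8.18, both also active in fat. Lung and airway markers rose with 10 of 10 positive and 8 passing over the list alone (camera adjusted p = 6.70e-08, adjusted p = 0.501 with an estimated correlation). Their high values were in pacing 2 and pacing 3, as for Sftpc above, while Scgb1a1 stood at 1.23 in pacing 1, 127 in pacing 2 and 1156 in pacing 3. Schwann cell and neuron markers rose with 8 of 9 positive (camera adjusted p = 0.00436, adjusted p = 0.423 with an estimated correlation). Neuropeptide Y, Npy, stood at 0.232 ± 0.384 and 1.87 ± 1.36. The Schwann call ended without pacing 2 (camera adjusted p = 0.0538).

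Erythrocyte and platelet markers rose with 6 of 7 positive and 5 passing over the list alone (camera adjusted p = 2.88e-06, adjusted p = 0.281 with an estimated correlation, fry adjusted p = 0.0324). Alas2, the first enzyme of heme synthesis in red cells, stood at 31.9 ± 10.3 in sham and 57.7 ± 5.75 in paced ventricles, and the beta-globin Hbb-bt at 38.9 ± 4.55 and 93.9 ± 44.7. The globin genes are near-identical copies, so that fragments can be split between them differently in each library, and the values of Hbb-bt, Hbb-bs and Hba-a2 are uncertain. Hba-a2 was the member with a negative fold change (log2 fold change -1.36, SE 2.05), at 33.5 ± 33.2 and 45.1 ± 77.9, and Hbb-bs had a log2 fold change of 3.67 (SE 1.0). The platelet gene Ppbp stood at 2.45 ± 0.586 and 4.04 ± 0.575, and the platelet gene Pf4 at 36.5 ± 4.14 and 37.9 ± 9.14.

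Atrial cardiomyocyte markers rose with 13 of 14 positive, 0 passing over the list alone and a median log2 fold change of 1.27 (camera adjusted p = 0.000201, adjusted p = 0.535 with an estimated correlation). The call ended without sham 2 (camera adjusted p = 0.308) and without pacing 2 and pacing 3 (camera adjusted p = 0.172). Myl7, the atrial myosin light chain, stood at 2700, 31.4 and 966 in sham 1, 2 and 3 and at 1141, 3520 and 2358 in pacing 1, 2 and 3, and sarcolipin, Sln, at 934, 12.2 and 359 and at 464, 1410 and 982. Atrial natriuretic peptide, Nppa, followed the same libraries, at 3629 ± 3474 and 5307 ± 1993 (log2 fold change 1.31, SE 0.93, limma adjusted p = 0.735).

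**Figure D2:**
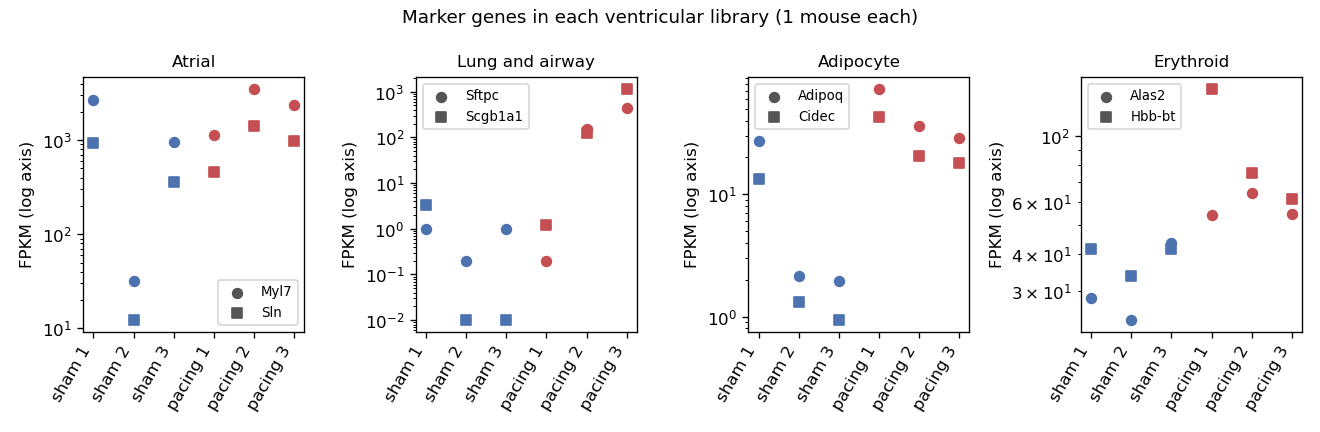
FPKM, on a log axis, of 2 marker genes each for atrial muscle, lung and airway, fat and red cells in the 6 libraries, with sham in blue and pacing in red. Atrial Myl7 ranges from 31.4 in sham 2 to 3520 in pacing 2, lung Sftpc lies above 100 in pacing 2 and pacing 3 alone, and Alas2 is higher in each paced mouse than in each sham mouse.

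Nuclear encoded respiratory chain genes fell by small, even amounts: 75 of 76 were lower, 0 passed over the list alone, and the median log2 fold change was -0.14 (camera adjusted p = 1.13e-11, adjusted p = 0.535 with an estimated correlation). Cytochrome c, Cycs, stood at 561 ± 15.7 in sham and 469 ± 24.3 in paced ventricles, Cox7a1 at 5314 ± 347 and 4365 ± 147, and Cox5a at 1702 ± 108 and 1421 ± 105. Genes of the citric acid cycle and mitochondrial biogenesis fell with 29 of 33 lower (camera adjusted p = 0.000134, adjusted p = 0.535 with an estimated correlation). Opa1 stood at 43.1 ± 4.24 and 35.7 ± 2.35. Glycolysis and glucose use genes fell with 30 of 32 lower (camera adjusted p = 0.000294, adjusted p = 0.535 with an estimated correlation). The pyruvate carrier Mpc2 stood at 579 ± 34.6 and 484 ± 24.8. Fatty acid oxidation genes fell with 26 of 29 lower (camera adjusted p = 0.00914, adjusted p = 0.610 with an estimated correlation). Plin5 stood at 92.9 ± 6.55 and 80.2 ± 6.00. Without sham 2 the citric acid cycle, glycolysis and fatty acid oxidation calls ended (camera adjusted p = 0.116, 0.0528 and 0.612), and the last also ended without sham 3 (0.0656), pacing 2 (0.0538) and pacing 3 (0.136). Sarcomere genes fell with 20 of 25 lower (camera adjusted p = 0.000213, adjusted p = 0.535 with an estimated correlation). Cardiac actin, Actc1, stood at 7757 ± 225 and 5997 ± 726 and troponin C, Tnnc1, at 5235 ± 660 and 4097 ± 288. Sarcomere genes did not pass after quantile normalization (camera adjusted p = 0.210). The mean log2 level of the respiratory chain genes was 10.132, 10.257 and 10.358 in sham 1, 2 and 3 and 10.138, 10.14 and 10.036 in pacing 1, 2 and 3. Sham 1 thus lay within the range of the paced mice, and sham 2 and sham 3 lay above it. The mean log2 level of all 15 adipocyte markers, tested or not, was 4.69, 3.23 and 2.79 and 5.50, 4.97 and 4.42. With the adipocyte level as a covariate the respiratory chain call ended (camera adjusted p = 0.305), and the sarcomere (0.277), glycolysis (0.876) and citric acid cycle lists (0.878) turned direction without passing. Fatty acid oxidation genes passed as higher with this covariate (0.0329), and did not pass after quantile normalization (0.264).

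Angiogenesis genes fell with 22 of 30 lower and 1, Aplnr, passing over the list alone (camera adjusted p = 3.42e-05, adjusted p = 0.331 with an estimated correlation). Its ligand Apln stood at 4.59 ± 0.469 in sham and 3.44 ± 0.686 in paced ventricles, the semaphorin receptor Nrp2 at 9.38 ± 1.27 and 7.23 ± 0.495, and the VEGF receptor Kdr at 34 ± 4.0 and 28.3 ± 1.56. Endothelial markers fell with 16 of 20 lower and 0 passing over the list alone (camera adjusted p = 0.00679, adjusted p = 0.501 with an estimated correlation). Icam2 stood at 36.4 ± 4.42 and 29.4 ± 3.30 and VE-cadherin, Cdh5, at 65.5 ± 11.1 and 53.2 ± 3.78. This call ended without sham 1 (camera adjusted p = 0.185), without pacing 1 (0.0577) and after quantile normalization (0.0519).

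**Figure D3:**
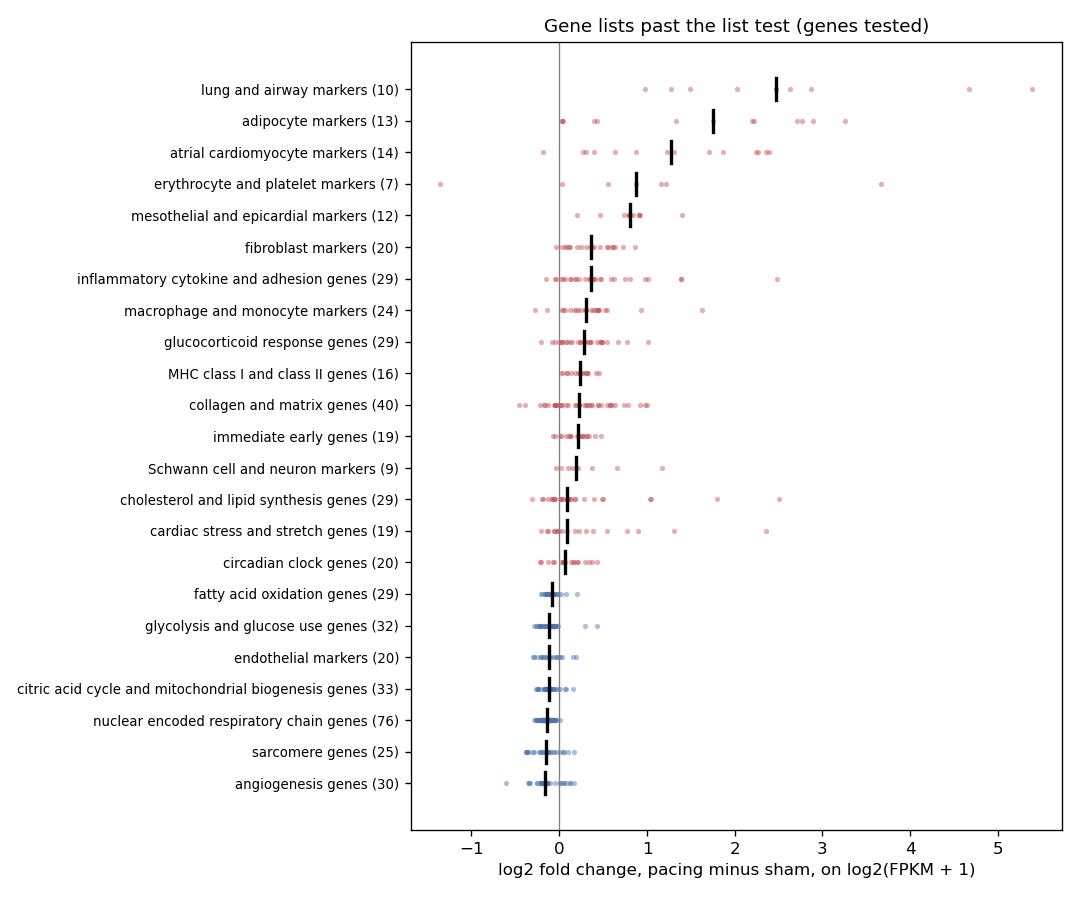
Log2 fold change of each tested member, as a point, of the 23 lists past the list test, with the list median as a black bar and the number of genes tested in brackets. Lists that rose are red and lists that fell are blue. Lung, adipocyte and atrial markers have the highest medians, at 2.47, 1.75 and 1.27, and angiogenesis genes the lowest, at -0.16.

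Cardiac stress and stretch genes rose with 12 of 19 positive and 1 passing over the list alone (camera adjusted p = 0.0305, adjusted p = 0.501 with an estimated correlation). The stress list did not pass without sham 1 (camera adjusted p = 0.0885) or without pacing 2 (0.199). Ctgf, a matrix protein induced by stretch, stood at 27.5 ± 4.53 in sham and 52.6 ± 12.1 in paced ventricles (log2 fold change 0.90, SE 0.18, limma adjusted p = 0.306), and Fhl1 at 65.2 ± 4.64 and 81.0 ± 4.45. Ankrd1, a sarcomeric stretch sensor, stood at 825 ± 31.4 and 968 ± 43.7, and the slow myosin heavy chain Myh7 at 14.7 ± 5.69 and 25.0 ± 6.08. Nppb, the B-type natriuretic peptide, stood at 115 ± 34.2 and 115 ± 15.4 (log2 fold change 0.03, SE 0.20). Circadian clock genes rose with 15 of 20 positive (camera adjusted p = 0.0435, adjusted p = 0.535 with an estimated correlation). Tsc22d3, which is also in the glucocorticoid list, stood at 56.1 ± 8.31 and 75.9 ± 8.73, and Per3 at 14.0 ± 1.01 and 16.2 ± 0.144. The median log2 fold change of the clock list was 0.06, and its member Clock was lower, at 4.84 ± 0.490 and 4.04 ± 0.183. Without a filter on low values neither the stress nor the clock list passed (camera adjusted p = 0.205 for both), and without a trend the clock list did not (0.0590). The clock call ended without sham 1 (camera adjusted p = 0.609), sham 3 (0.0556), pacing 2 (0.0642) and pacing 3 (0.111).

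Of the 24 genes of a fixed panel of load, rhythm, matrix and clock readouts, 0 passed over all genes. The calcium pump Atp2a2 had a log2 fold change of -0.17 (SE 0.12) and the calcium release channel Ryr2 of -0.29 (SE 0.15). The potassium channel gene Kcnd2 differed by -0.11 (SE 0.13), its partner Kcnip2 by -0.06 (SE 0.17), and the gap junction gene Gja1 by -0.22 (SE 0.13). Myh6 differed by -0.18 (SE 0.16), Acta1 by 0.39 (SE 0.31), Pdk4 by -0.09 (SE 0.15), Hmox1 by 0.18 (SE 0.15), Fos by 0.47 (SE 0.25) and Egr1 by 0.07 (SE 0.31). Collagen Col1a1 differed by 0.60 (SE 0.24), Postn by 0.58 (SE 0.22) and Timp1 by 0.55 (SE 0.32), and without sham 1 Col1a1 and Postn passed (limma adjusted p = 0.00763 and 0.0295). Col1a1 stood at 27.8, 13.7 and 13.5 in sham 1, 2 and 3 and at 25.9, 25.2 and 29.4 in pacing 1, 2 and 3. Postn stood at 35.1, 17.9 and 21.0 and at 37.1, 30.9 and 40.1. In both genes sham 1 alone of the sham mice lay within the paced range. Leaving it out favours a pass, so these passes do not settle the difference. The clock genes Per1, Dbp and Nr1d1 differed by 0.29 (SE 0.18), -0.08 (SE 0.14) and -0.22 (SE 0.19). Gdf15 lay below the filter, at 0.315 ± 0.269 and 0.0891 ± 0.0688, with an exact two-sided permutation p of 0.4, where 3 mice against 3 cannot go below 0.1.

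The other 19 lists did not pass. Cardiac ion channels and gap junctions were divided, with 13 of 31 higher (camera adjusted p = 0.911), as were beta adrenergic signalling genes, with 18 of 32 higher (0.344). Growth factor and exercise response genes had 16 of 36 higher (0.679), p53 and apoptosis genes 11 of 27 (0.395) and heat shock genes 8 of 22 (0.301). Hypoxia response genes had 10 of 25 higher (0.271), skeletal muscle markers 4 of 7 (0.873), and nuclear retained transcripts, a sign of RNA quality, 3 of 6 (0.348). Smooth muscle and pericyte markers had 8 of 16 higher (0.363), with 4 passing over the list alone, and the contractile genes Lmod1, at 1.64 ± 0.180 and 3.43 ± 0.531, and Tagln, at 36.1 ± 11.5 and 73.4 ± 12.2, among them. Their median, -0.02, and mean, 0.20, differ in sign, as do those of PPAR target genes (-0.08 and 0.10, camera adjusted p = 0.496, direction lower), growth factor genes (-0.03 and 0.01, direction lower), ion channels (-0.03 and 0.02, direction lower) and muscle protein turnover genes (0.00 and -0.01, direction lower, camera adjusted p = 0.696). Several of these lists passed without a particular mouse: calcium handling genes (23 of 33 lower, 0.121 with all mice) without sham 3 (0.0391) and oxidative stress genes (29 of 40 higher, 0.0616) without sham 3 (0.00774) or pacing 3 (0.0228). So did endoplasmic reticulum stress genes (18 of 29 higher, 0.0925) without sham 3 (0.0483) or pacing 2 (0.0182), and cell cycle genes (11 of 17 lower, 0.0549) without sham 2 (0.00834), sham 3 (0.0488) or pacing 3 (0.0357). Interferon response genes (28 of 44 lower, 0.249) passed without sham 2 (1.63e-05) and with the atrial (7.71e-07) or adipocyte covariate (2.69e-12). Conduction system markers (8 of 12 higher, 0.301) passed without sham 1 (0.00897), renin angiotensin and natriuretic peptide genes (13 of 18 higher, 0.227) without pacing 1 (0.0287) and muscle protein turnover genes without sham 1 (0.0384). Rescaling or quantile normalization also brought oxidative stress genes (0.0201 and 0.00463), cell cycle genes (0.0221 and 0.0155, with 0.0135 and 0.0430 without a filter and without a trend) and ribosomal protein genes (0.00411 and 2.40e-06) past the threshold, and quantile normalization endoplasmic reticulum stress genes (0.042). Ribosomal protein genes (46 of 76 higher, 0.435) passed without sham 3 (5.78e-06) and, as lower, without sham 2 (0.00134).

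The libraries correlated across genes at 0.980 to 0.987 within sham, 0.985 to 0.990 within pacing and 0.973 to 0.988 between the groups. The first principal component held 44.2% of the variance and set sham 2 and sham 3, at 27.1 and 17.0, apart from the other 4 libraries, at -18.1 to -5.30. Among the genes that the authors' deposited table called higher, sham 1 was the highest sham mouse in 85.9% and sham 2 the lowest in 64.0%, where 33.3% would be expected if each sham mouse were as likely. Many of these genes vary together and the share over all tested genes was not computed, so 33.3% is only a rough reference.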

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

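The tests of the atrial, lung and fat markers were chosen after the results were seen, while the counts over other splits of the mice were planned. For the tests of whether pacing raised atrial or lung genes, the bounds that would have excluded this were narrowed after the counts of 0 and 5 were known, since each count rests on a single library. What would have favoured unequal atrial tissue, lung carry-over or unequal fat was also made stricter after their values were known. In the authors' deposited table, 2 called rows each merge globin genes, and these merged rows have no value per mouse and so entered no comparison: Hba-a1,Hba-a2 stood at 1833 in the sham and 3283 in the pacing group (log2 fold change 0.84), and Hbb-b1,Hbb-bs at 1608 and 3092 (log2 fold change 0.94), each above the level of the sham controls. They lie in the same direction as Alas2, and the table gives no spread between mice for them.

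Atrial markers differed strongly between ventricular samples, within the sham group too, where Myl7 stood at 2700, 31.4 and 966. If unequal amounts of atrial tissue were the source, the other atrial markers should shift with Myl7 among the sham mice, and the median slope of 13 markers on Myl7 over those mice was 0.676, with a range from 0.10 to 0.97. These markers had been seen to vary together, and shared regulation would give it too, so the slope does not decide. Bmp10, known for the right atrium, stood at 67.8, 0.220 and 38.6 in sham 1, 2 and 3 and at 38.1, 16.8 and 28.7 in pacing 1, 2 and 3. If pacing had raised atrial genes, paced mice should lie above sham mice, and 0 of 14 markers had all 3 paced values above all 3 sham values, although leaving out a sham mouse raised this to as many as 11, so that pacing and unequal tissue cannot be told apart.

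Lung transcripts were high in pacing 2 and pacing 3. Of 11 lung markers, 9 lay above FPKM 1 in both and above each other library, a count on the transcripts that drew attention, which therefore does not decide whether lung tissue was carried over. Sftpc, among the most abundant transcripts of lung, stood at 153 and 430 there. If pacing had raised lung genes, pacing 1 should show them, and 5 of 11 markers were higher in pacing 1 than in each sham mouse, with 2 of these above FPKM 1 and the highest lung marker there at 2.18. This rests on 1 paced mouse, so a response to pacing in part of the mice cannot be told apart from carry-over.

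Fat markers were higher in paced mice, and sham 1 lay above the other sham mice. If unequal amounts of fat tissue were the source, the spread within sham should be as large as the difference between groups. Over the 13 tested adipocyte markers, the range of the mean level within sham was 1.42 times that difference, at 2.18 against 1.54 on the log2 scale. Without sham 1 that ratio was 0.222, at 0.49 against 2.19, so it rests on this mouse. If pacing had raised adipocyte genes, most markers should separate the groups, and 4 of 13 did, or 8 without sham 1, so that pacing cannot be told apart from unequal fat in these mice. With the adipocyte level as a covariate, the lists higher went from 16 to 10. This level itself differs between the groups, so the change does not tell fat from pacing.

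Over the 10 ways to split the 6 mice into 3 and 3, the real count at an adjusted p under 0.05 was 0 genes, which all 10 reach by construction, so this count says nothing about chance. The highest of the others was 1. At an unadjusted p, 2 of the 10 splits reached the real count of 1062 genes, and the highest other, 1264, set sham 1, pacing 2 and pacing 3, the 3 libraries with the most Myl7, against the rest. For lists, 1 of the 10 splits, the real one, gave 23. The others, each of which mixes sham and paced mice, gave from 8 to 20 lists. With 10 splits the share cannot fall under 0.05.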

How the results depend on the processing

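The atrial and adipocyte covariates and the fit without pacing 2 and pacing 3 were chosen after seeing the data. Genes higher numbered 0 in most settings, 7 with a replicate block, 1 with robust eBayes and 0 to 99 with 1 mouse left out, and genes lower 0 to 1 with 1 mouse left out. The replicate block raised the count from 0 to 7 and changed no list count. Deviations of same-numbered mice from their group means correlated at -0.125, -0.022 and -0.020. These values give no sign that the numbers pair the mice, but with 3 mice per group they cannot exclude a weak pairing. Lists higher went from 16 to 0 with an estimated correlation, 1 with fry, 10 with the atrial covariate and 10 with the adipocyte covariate, and 14 to 17 with 1 mouse left out. Lists lower went from 7 to 0 with an estimated correlation, 0 with fry and 4 without pacing 2 and pacing 3, where the lone paced mouse is assumed to vary like the sham mice, and 6 to 8 with 1 mouse left out. Calls of the authors' deposited table went from 299 higher and 37 lower to 201 and 11 at a q under 0.01 and to 114 and 1 with a log2 fold change of at least 1. Of the 23 passing lists, 6 kept their call in all settings with the preset correlation that gave a value: inflammatory, immediate early, angiogenesis, glucocorticoid, erythrocyte and lung. Of 878 values of the lists under alternatives, 54 changed sign, and 15 of these passed in the main fit, under the alternative, or in both. Only the 15 are named here. With the adipocyte covariate these lists turned direction, with camera adjusted p in brackets: sarcomere (0.277), collagen (0.0218), fatty acid oxidation (0.0329), glycolysis (0.876), citric acid cycle (0.878), MHC (0.0891), muscle protein turnover (0.0149), cholesterol and lipid synthesis (0.878), atrial (0.391), macrophage (0.125) and adipocyte markers (0.152), the last of which holds the covariate's own genes. With the atrial covariate fatty acid oxidation (0.509), ribosomal (0.00189) and atrial markers (0.620) turned, and ribosomal genes turned without sham 2 (0.00134), over a range of 5.78e-06 to 0.748 with 1 mouse left out. The cause was not tested. Of 3643 values of 168 named genes under alternatives, 0 passed in the other direction, 38 passed that had not, and 53 changed sign without passing, which was counted as no change. At these depths an FPKM of 1 stands for few fragments, so counting error limits the lowest genes.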

Other observations

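The genes here were picked after their values were seen, except Tfrc, Hsp90aa1 and Hspb6. Tfrc, through which cells take up iron, stood at 40.5, 19.6 and 24.4 in sham 1, 2 and 3 and at 9.53, 18.4 and 12.7 in pacing 1, 2 and 3 (log2 fold change -0.98, SE 0.28, limma adjusted p = 0.428). The brown fat gene Ucp1 stood at 21.1, 3.34 and 1.08 in the sham mice and at 48.6, 30.2 and 1.06 in the paced mice, so that pacing 3, with Adipoq at 28.6, had a Ucp1 level like that of sham 3. Of heat shock genes, Hsp90aa1 stood at 54.1 ± 3.05 and 68.1 ± 4.34, while Hspb6 stood at 829 ± 44.0 and 711 ± 39.8. The neutrophil gene S100a9 stood at 23.6 in pacing 1 and at 1.46 and 5.96 in pacing 2 and pacing 3, against 0.715 to 2.21 in the sham mice.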
